A study of Mus musculus with 14 samples.

How the data were processed

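The series holds 14 Affymetrix arrays of whole inguinal mammary glands (number 4) from untreated female CD1 mice, 3 each at 3, 4, 6 and 7 weeks and 2 at 5 weeks, per the labels. Each array was hybridised with biotin-labelled RNA made from a pool of at least 3 mice, and whether any mouse gave RNA to more than 1 pool is not given in the sources used here. The arrays of an age were taken as replicates, so p-values measure the spread between pools, which averages over mice.

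The deposited table gives linear ratios: tests on the values showed that 98.48% of the 22690 probe sets have a median over the 14 arrays of 1 within 0.001, so the authors had divided each probe set by its own median. The 337 probe sets whose median lies below 0.98 look as if a minimum divisor had been used for them. Values ran from 0.01, which 9 of them took, to 38.13, and the array medians from 0.953 to 1.017. The software that made the signals, and any scaling of it, are not given in the sources used here. Dividing by the median removed the absolute signal, so levels cannot be set against each other between genes. For 6077 probe sets (26.78%) the ratios were whole multiples of a step, from which the level before division was recovered, and in simulated data the recovery was wrong for 0.08% of probe sets in the lowest range. Detection calls were not used here.

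Values were put on the log2 scale with no offset. The array medians differed by at most 0.0938 on that scale, below the limit of 0.2 set before the data were examined, so no further normalization was applied. The 64 control probe sets were left out, as were 4091 probe sets whose recovered level was below 200 steps on all arrays or on all but 1, which left 18535 tested. 3 points differ from the design fixed before the data were examined, which had assumed signal values: an offset of 16 was dropped because it would swamp ratios, the filter on the 40th percentile became the filter on recovered level, and a gene was represented by the mean of its probe sets, since ratios cannot show which probe set is brightest. Gene names came from the platform annotation: 20380 probe sets name 1 gene, 691 several and 1555 none, and 20364 matched the RefSeq table of GRCm38.p6 by gene identifier, with 0 symbols changed. No gene was named from a probe set with several, and 10703 genes were tested of 12394 named.

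One linear model with age as a factor was fitted to all 14 arrays with limma 3.58.1 in R 4.3.3, and empirical Bayes moderation gave an F test over the 5 ages and 7 comparisons: each later age against 3wk and each week against the one before. Because all ages share 1 estimate of the spread, the age with 2 arrays could be tested. Benjamini-Hochberg adjustment was applied within each comparison, with a threshold of 0.05. All tests are two-sided. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

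The 26 gene lists were fixed before the data were examined: luminal and pan-epithelial, basal and myoepithelial, hormone-responsive, milk, cell cycle, adipocyte, brown adipocyte, fatty acid synthesis, cholesterol synthesis, oxidative phosphorylation, fibrillar matrix, basement membrane, macrophage, lymphocyte, skeletal muscle, endothelial, skin keratinocyte, branching, matrix protease, interferon, immediate early, circadian, erythroid, Schwann cell, imprinted and insulin-like growth factor genes. Of their 665 entries 563 were tested, 39 were below the filter and 63 were not analysed here. They were tested with camera of limma, preset correlation 0.01, on the gene values, adjusted over all 182 tests. Of these, 79 were called, 40 upwards and 39 downwards. With a correlation estimated from the data none of the 79 held, the lowest adjusted p being 0.0774. fry, which asks only whether a list's genes move one way on balance, called 54.

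Genes were named by a rule set in advance: for 7wk against 3wk the 12 largest rises and 12 largest falls, for other comparisons the 4 largest of each, among called probe sets that name 1 gene with no overlap between the ages and a mean ratio at the higher age of at least the median. This last bound was meant for signal values, and on ratios it sets no limit on the level. The rule also takes up to 4 members of each list described, the 10 smallest adjusted p of the F test, and 11 genes: Areg, Esr1, Pgr, Krt8, Krt14, Csn2, Wap, Mki67, Adipoq, Ucp1 and Igf2.

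The 5' to 3' log2 ratios of the actin and pyruvate carboxylase control probe sets and the mean of 18 hybridisation control probe sets were taken as signs of RNA quality and handling. The same ratios for Gapdh and the transferrin receptor were computed too. Control probe sets had also been divided by their own medians. These values therefore compare arrays only, and a ratio of 0 does not mean equal 5' and 3' signal. No 2 arrays held identical values. The model was tested on simulated data with 200 of 18535 probe sets changed: for 7wk against 3wk it called 46.3%, 82.1% and 97% of those changed 2-, 4- and 8-fold, and 0.7% of its calls were false. That share was 1.4% for 4wk against 3wk, 4.4% for 6wk against 3wk and 4.3% for 5wk against 4wk. It was above the 5% aimed at for 5wk against 3wk (6.4%), 6wk against 5wk (6.2%), 7wk against 6wk (8.3%) and any age (5.5%), in 1 simulation. In simulated gene lists 6 of 6 shifted by 1.5-fold and 0 of 176 not shifted were called. The simulated genes varied independently of each other, so false list calls from genes that move together were not covered. Alternatives tried were quantile normalization, median centring, no filter, offsets of 1 and 64, array weights, the array letter as a block, a 2-fold bound, fits of 2 ages alone, each array left out in turn, and set tests with an estimated correlation. Chosen after the data were seen were a filter of 400 steps, offsets of 16 and 0.1, a robust fit, 6wk A and B left out, the control spikes as a covariate, and 1 probe set per gene. The splits of the arrays were 100 groupings for the F test and lists, of which 1 was the real one and the others random, and all 10 splits of each comparison of 3 against 3 arrays.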

Results

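Whole inguinal mammary glands (number 4) of female CD1 mice, an outbred strain, were profiled on Affymetrix expression arrays at 3, 4, 5, 6 and 7 weeks of age, a span that the series title places in puberty. Lymph nodes had been taken out of the glands before RNA was extracted, and each array carried RNA pooled from at least 3 mice. There were 3 arrays (A, B and C) at 3wk, 4wk, 6wk and 7wk and 2 (A and B) at 5wk, 14 in all. The values are ratios of each probe set to its own median over the arrays, so they compare ages within a gene and carry no level between genes. The number of arrays limits the precision, and a fold against an age near the background of the array depends on that background. The genes named for the largest changes are given as 1 probe set, and the members of gene lists and the 11 genes fixed in advance as the mean over the probe sets of the gene, so that a gene such as Csn2 or Sox9 can appear with a value of each kind. Changes are log2 differences with the standard error (SE) of the fit, n = 3 arrays per age except n = 2 at 5wk.

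Across the 5 ages, the 10 probe sets with the smallest adjusted p were 8 with lower mean ratios at 3wk than at 5wk, 6wk or 7wk and 2, Ppara and Acaa2, that went down. Mycl, a transcription factor of the MYC family, had mean ratios of 0.115 ± 0.0290 (SD, n = 3) at 3wk, 0.0952 ± 0.00603 at 4wk and 1.31 ± 0.252 (n = 2) at 5wk. Elf5, a transcription factor of luminal and alveolar mammary epithelium, went from 0.165 ± 0.0197 at 3wk through 0.393 ± 0.0845 at 4wk to 1.53 ± 0.150 at 6wk. Csn1s2a, which encodes a casein of milk, stood at 0.0436 ± 0.0141 at 3wk and 13.5 ± 5.50 at 7wk. Ppara, the nuclear receptor that drives fatty acid oxidation, fell from 7.94 ± 3.04 at 3wk to 0.176 ± 0.0361 at 6wk and 0.432 ± 0.0874 at 7wk, and Acaa2, a thiolase of mitochondrial beta-oxidation, from 2.52 ± 0.0849 at 3wk to 0.811 ± 0.0509 at 7wk. The other 5 of the 10 were Pla1a, a phospholipase, Gnaz, a G protein subunit, Tnk1, a tyrosine kinase, Stc2, a secreted glycoprotein responsive to oestrogen, and Acot1, an acyl-CoA thioesterase. All 5 had lower mean ratios at 3wk than at 5wk, 6wk or 7wk (Stc2 0.310 ± 0.0211 at 3wk and 1.31 ± 0.173 at 7wk, for example).

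In limma's F test over the 5 ages, 1904 of 18535 probe sets differed (adjusted p under 0.05; 1153 of 10703 genes), against 5116 at an unadjusted p under 0.05. Among the 1904, the mean was lowest at 3wk for 877 (46.1%), against 26.1% of the probe sets that were not called, and highest at 6wk for 607 (31.9%, against 25.9%). The actin and pyruvate carboxylase controls of RNA quality moved with age: the log2 ratio of the 5' to the 3' actin control probe sets averaged 0.07 ± 0.12 (SD) at 3wk, 0.20 ± 0.10 at 4wk, −0.21 ± 0.07 at 5wk, −0.45 ± 0.35 at 6wk and 0.11 ± 0.06 at 7wk. The same ratio for pyruvate carboxylase was −0.09 ± 0.51, 0.33 ± 0.21, −0.95 ± 0.42, −2.37 ± 0.50 and 0.82 ± 0.08. The transferrin receptor ratio did not follow them, at −0.643, −0.574 and −0.855 on 3wk A, B and C and 0.066, −0.738 and −0.335 on 6wk A, B and C. For Gapdh the 6wk arrays stood at −0.566, −0.097 and −0.031, against 0.084, −0.011 and 0.027 at 3wk. The count was 1012 without 6wk A and B, the arrays with the lowest actin ratios, which leaves 1 array at 6wk, and 1033 with the mean of the hybridisation control spikes as a covariate.

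Between 3wk and 7wk, the ends of the series, genes of milk and of the mammary epithelium rose. The caseins had the largest rises: Csn1s2a by 8.22 (SE 0.57), Csn2 by 6.99 (SE 0.57) and Csn1s1 by 6.70 (SE 0.58). Chil1, a secreted chitinase-like glycoprotein, rose by 5.60 (SE 0.39), Muc1, the mucin of the apical surface of secretory epithelium, by 5.47 (SE 0.83), and Igha, the heavy chain of immunoglobulin A, by 4.63 (SE 0.42). The other rises named by the rule were B4galnt1, a glycosyltransferase of ganglioside synthesis (4.57, SE 0.97), the cytokine Il17b (4.42, SE 0.80), Mal2, a protein of apical transport (4.33, SE 0.51), Wif1, a secreted inhibitor of Wnt (4.31, SE 0.84), the tight junction protein Cldn8 (4.12, SE 0.62) and the transcription factor Sox9 (3.93, SE 0.66). Adjusted p for these 12 ran from 4.08e-05 for Csn1s2a to 0.0146 for B4galnt1. The rule by which they were named required no overlap between the 3wk and 7wk arrays.

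Of 28 tested luminal and pan-epithelial genes, 27 rose from 3wk to 7wk and none fell (28 rose when adjusted over the list alone), among them Muc1, the serine protease Prss8 (3.56, SE 0.68), the adhesion molecule Epcam (3.05, SE 0.27) and Elf5 (2.91, SE 0.29). The list's median was 1.86 and camera's adjusted p 4.26e-26, with adjusted p = 0.101 with an estimated correlation. Milk protein and secretory genes rose in 11 of 18 (13 adjusted over the list alone; median 1.53), led by Csn1s1, Csn2 (6.22, SE 0.55, over its probe sets), Csn1s2a (5.12, SE 0.47, over 3 probe sets of which 1 stood at −0.29) and Btn1a1, the butyrophilin of the milk fat globule (3.32, SE 0.30). Camera's adjusted p was 1.55e-08, and adjusted p = 0.101 with an estimated correlation. In the basal and myoepithelial list, 7 of 19 rose (10 adjusted over the list alone; median 0.91), among them the smooth muscle protein Cnn1 (2.74, SE 0.29), while Col17a1, a collagen of hemidesmosomes, did not pass (2.27, SE 1.12). Camera gave an adjusted p of 2.09e-05, and adjusted p = 0.153 with an estimated correlation. Hormone receptor and hormone-responsive genes rose in 7 of 20 (10 rose and 1 fell when adjusted over the list alone; median 0.99), with Wnt4, a signal induced by progesterone, at 3.12 (SE 0.68), Gata3, a luminal transcription factor, at 2.75 (SE 0.43), Stc2 at 2.56 (SE 0.17) and Foxa1, a cofactor of the oestrogen receptor, at 2.23 (SE 0.26). Their adjusted p by camera was 0.000157, and adjusted p = 0.158 with an estimated correlation.

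Branching and guidance signals rose in 10 of 41 (11 adjusted over the list alone; median 0.39), including Sox9 (3.02, SE 0.39), the growth factor Tgfb3 (2.27, SE 0.31) and the heparin-binding growth factor Ptn (2.06, SE 0.27). The camera test gave an adjusted p of 0.00114, and adjusted p = 0.12 with an estimated correlation. Among 23 matrix proteases and inhibitors, 8 rose and 2 fell (10 and 2 adjusted over the list alone; median 0.66), with rises of the metalloproteinases Mmp3 (1.47, SE 0.24) and Mmp2 (1.37, SE 0.16) and of Plat, the tissue plasminogen activator (1.24, SE 0.14). The adjusted p from camera was 0.000899, and adjusted p = 0.246 with an estimated correlation. Immediate early and stress genes rose in 7 of 29 (8 adjusted over the list alone; median 0.42), among them Maff (2.93, SE 0.52), a small MAF transcription factor, the heat shock genes Hspa1b (2.62, SE 0.21) and Hspa1a (1.60, SE 0.34), and Fos (1.15, SE 0.23). For this list camera gave 0.00215, and adjusted p = 0.158 with an estimated correlation. The list had been fixed in advance as a check on handling. Its mean was −0.438, −0.285, 0.125, 0.120 and 0.136 at 3wk, 4wk, 5wk, 6wk and 7wk. A difference in handling between ages and a change of the gland are not told apart here.

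Of the 12 largest falls from 3wk to 7wk, 5 belong to the brown adipocyte list (Ppara, Fabp3, Slc27a2, Cox7a1 and Ucp1). Agt, angiotensinogen, stood at −4.23 (SE 0.44), Ppara at −4.15 (SE 0.33) and the fatty acid binding protein Fabp3 at −4.11 (SE 0.34). Slc27a2, a transporter and activator of long fatty acids, fell by 4.05 (SE 0.75) and Cox7a1, a subunit of cytochrome c oxidase, by 3.33 (SE 0.27). Ucp1, the uncoupling protein that makes heat in brown fat, fell by 3.01 (SE 0.57). The others were Anxa8 (−3.30, SE 0.33), an annexin, the cytokine Il21 (−3.11, SE 0.72), Cpn2 (−3.05, SE 0.57), a carboxypeptidase subunit, the apolipoprotein Apoc4 (−2.81, SE 0.74), the bicarbonate transporter Slc4a4 (−2.79, SE 0.38) and Klkb1, plasma kallikrein (−2.73, SE 0.73). Adjusted p for the 12 ran from 7.49e-05 to 0.0414.

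Brown adipocyte genes fell in 8 of 13 and rose in none (9 fell when adjusted over the list alone; median −1.43), with Ppara, Fabp3, Slc27a2 and Cox7a1 moving most. Camera's adjusted p was 1.38e-10, and adjusted p = 0.0774 with an estimated correlation. Of 37 genes of oxidative phosphorylation and the citric acid cycle, 25 fell (31 adjusted over the list alone; median −0.64), among them Cyc1 (−1.12, SE 0.14), cytochrome c1, and Sdhb (−0.96, SE 0.15), a subunit of succinate dehydrogenase. By camera the adjusted p was 1.69e-26, and adjusted p = 0.101 with an estimated correlation. General adipocyte genes moved less: 5 of 21 fell and 2 rose (9 and 3 adjusted over the list alone; median −0.35), with Fabp4, the fatty acid binding protein of fat cells, at −0.68 (SE 0.15), Orm1, an acute phase protein, at 0.90 (SE 0.17), and the hormone adiponectin, Adipoq, at −0.43 (SE 0.10). The adipocyte list had, by camera, an adjusted p of 0.000181, and adjusted p = 0.12 with an estimated correlation. Imprinted growth genes fell in 4 of 13 (5 adjusted over the list alone; median −0.31), among them Nnat (−1.52, SE 0.44), Dlk1 (−1.24, SE 0.29) and Plagl1 (−0.97, SE 0.15). By camera the adjusted p was 3.63e-05, and adjusted p = 0.0774 with an estimated correlation.

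In all, camera called 7 lists upwards and 9 downwards between 3wk and 7wk, 5 of them not yet named. Interferon response genes fell in 2 of 25 (5 adjusted over the list alone; median −0.41), among them the guanylate-binding protein Gbp3 (−1.29, SE 0.35). In camera the list had an adjusted p of 2.65e-05, and adjusted p = 0.21 with an estimated correlation. Cell cycle genes had a median of −0.27, with 1 of 35 falling, the cyclin Ccne2 (−0.77, SE 0.21; 0 adjusted over the list alone), but the list's means overlapped between the ages (−0.706, 0.116 and −0.048 on 3wk A, B and C, and −0.710, −0.698 and 0.055 on 7wk A, B and C). The camera test gave an adjusted p of 0.000648, and adjusted p = 0.604 with an estimated correlation. In the erythroid list 2 of 7 fell (3 fell and 1 rose when adjusted over the list alone), Alas2, the first enzyme of haem synthesis in red cells (−1.93, SE 0.25), and the transferrin receptor Tfrc (−1.48, SE 0.21). The adjusted p by camera was 0.0125, and adjusted p = 0.179 with an estimated correlation. Schwann cell genes fell in 3 of 9 and 1 rose (3 and 1 adjusted over the list alone), with the myelin protein Mbp at −1.19 (SE 0.16) and the transcription factor Sox10 at 1.13 (SE 0.26). By camera the adjusted p was 0.016, and adjusted p = 0.246 with an estimated correlation. Endothelial genes had a median of −0.20 although 1 of 22 rose, the clotting factor Vwf (0.95, SE 0.21; 1 adjusted over the list alone). By camera the adjusted p was 0.0136, and adjusted p = 0.427 with an estimated correlation. The array means of the endothelial and Schwann cell lists overlapped between the ages as well, and both lists lost their call without 3wk A.

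The other 10 lists were not called between 3wk and 7wk, though single members passed. Fatty acid synthesis genes rose in 4 and fell in 2 of 21 (median 0.28, camera 0.0939), with Elovl6 at 2.10 (SE 0.21) and Pdk4, a brake on glucose oxidation, at −1.25 (SE 0.33), and cholesterol synthesis genes in 0 of 19 (median 0.17, camera 0.635). Fibrillar matrix genes rose in 1 and fell in 4 of 29, among them Pcolce, an enhancer of collagen maturation (−1.03, SE 0.22), with camera at 0.266, and the median of 0.07 had another sign than the mean of −0.01. In the basement membrane list 3 of 18 fell, among them Nid2 (−0.95, SE 0.26) and the collagen Col4a2 (−0.63, SE 0.15), with camera at 0.196, a median of 0.14 and a mean of −0.04. Macrophage genes rose in 1 and fell in 1 of 28 (median 0.31, camera 0.0813), with Cd14, a receptor for bacterial lipid, at 1.30 (SE 0.18), and lymphocyte genes rose in 1 of 24 (median 0.23, camera 0.514), Jchain, which joins immunoglobulin A (2.71, SE 0.42). Skeletal muscle genes changed in 0 of 14 (median −0.11, camera 0.222; Tnnt3, a troponin, −1.55, SE 0.65), and skin keratinocyte genes fell in 1 of 14, Krt6a (−0.98, SE 0.25), with camera downwards at 0.855, a median of 0.27 and a mean of 0.05. Circadian genes rose in 2 and fell in 2 of 17, with Npas2, a clock transcription factor, at 2.12 (SE 0.59), camera downwards at 0.643, a median of 0.05 and a mean of 0.11. Genes of the insulin-like growth factor and growth hormone axis rose in 2 of 19, the binding proteins Igfbp5 (1.33, SE 0.19) and Igfbp6 (1.16, SE 0.29), with camera downwards at 0.454, a median of −0.12 and a mean of 0.04.

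**Figure D1:**
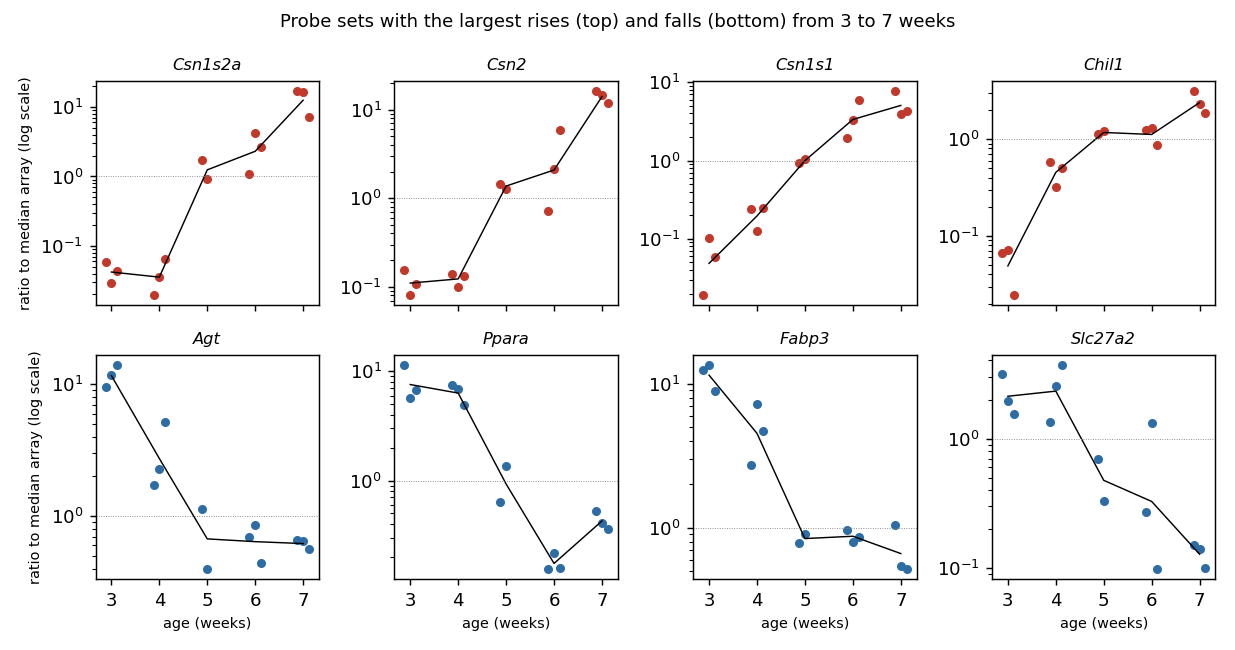
Ratio of 8 probe sets to their own median over the 14 arrays, on a log axis, against age in weeks: Csn1s2a, Csn2, Csn1s1 and Chil1 above, Agt, Ppara, Fabp3 and Slc27a2 below. Each point is 1 array and each line joins the geometric means of the ages. The arithmetic mean ratio, which the line does not show, goes from 0.0436 at 3wk to 13.5 at 7wk for Csn1s2a and from 7.94 to 0.432 for Ppara.

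Krt8, a keratin of luminal cells, rose by 1.62 (SE 0.34) from 3wk to 7wk and Krt14, a keratin of basal cells, by 1.43 (SE 0.21), though 1 of the 3 Krt14 probe sets stood at 0.09 (SE 0.34). The receptors Esr1 (0.32, SE 0.68) and Pgr (SE 0.50, adjusted p = 0.24), the milk protein Wap (−0.32, SE 0.28), the proliferation marker Mki67 (−1.29, SE 0.45) and the growth factor Igf2 (0.11, SE 0.53) passed the test neither here nor in the other 6 comparisons. Areg was not analysed here. In total 1575 probe sets were called, 1096 higher and 479 lower at 7wk (1074 genes), with 4200 at an unadjusted p under 0.05, and 28.3% of all probe sets had no overlap between the ages, against 10% by chance. The hybridisation control spikes averaged 0.15 ± 0.40 (SD) at 3wk and −1.21 ± 0.58 at 7wk, and with them as a covariate 351 probe sets were called. The count was 928, 970 and 923 without 7wk A, B or C; B4galnt1 lost its call without 3wk A, and Il21, Apoc4, Klkb1 and Adipoq lost theirs in 5, 7, 10 and 4 of the 14 fits that left out 1 array.

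**Figure D2:**
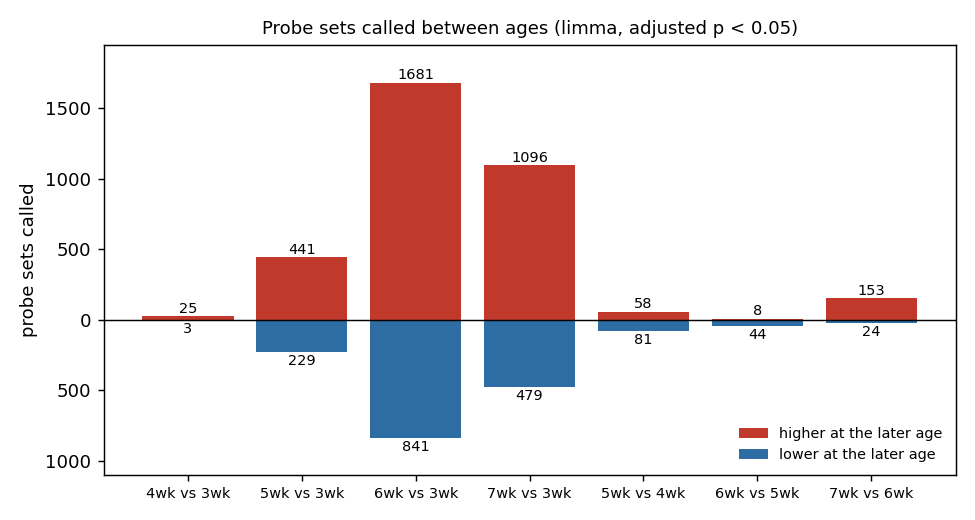
Number of probe sets called (limma, adjusted p under 0.05) in each of the 7 comparisons of ages, as bars of those higher and those lower at the later age. The count ran from 28 for 4wk against 3wk to 2522 for 6wk against 3wk.

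At 6wk, against 3wk, Csn1s1 and Csn1s2a were again among the largest rises, and Ppara and Agt among the largest falls. Il17b was higher by 6.20 (SE 0.80), Csn1s1 by 6.10 (SE 0.58), Csn1s2a by 5.78 (SE 0.57) and Clca1, a secreted regulator of chloride channels, by 4.63 (SE 0.82). The probe sets of Csn1s2a disagreed here, since another of them fell by 0.96 (SE 0.24). Among the falls, Ppara stood at −5.45 (SE 0.33) and Kcnk3, a potassium leak channel, at −4.53 (SE 0.41). Malat1, a nuclear noncoding RNA, was at −4.46 (SE 0.53) and Agt at −4.19 (SE 0.44). Of the genes fixed in advance, Krt8 rose by 1.96 (SE 0.34), Krt14 by 1.65 (SE 0.21; −0.05 at 1 of its probe sets) and Csn2 by 3.64 (SE 0.55), and Ucp1 fell by 2.40 (SE 0.57).

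Camera called 7 lists upwards and 7 downwards between 3wk and 6wk, none with an estimated correlation. Luminal genes rose in 26 of 28 (26 adjusted over the list alone; Prss8 3.52, SE 0.68). In camera the list had an adjusted p of 5.8e-22, and adjusted p = 0.101 with an estimated correlation. Basal genes rose in 12 of 19 (15 adjusted over the list alone; median 1.35), including Col17a1 (3.71, SE 1.12) and Cnn1 (3.47, SE 0.29). In camera the list had an adjusted p of 9.21e-08, and adjusted p = 0.101 with an estimated correlation. Milk genes rose in 12 of 18 (12 rose and 1 fell when adjusted over the list alone). By camera the adjusted p was 2.11e-06, and adjusted p = 0.12 with an estimated correlation. Brown adipocyte genes fell in 9 of 13 (10 adjusted over the list alone; median −1.74) and oxidative phosphorylation genes in 29 of 37 (32 adjusted over the list alone; median −0.61). Camera's adjusted p were 1.16e-10 and 5.3e-20, against adjusted p = 0.0774 with an estimated correlation for the first and adjusted p = 0.104 with an estimated correlation for the second. In the adipocyte list 5 of 21 fell and 2 rose (8 and 3 adjusted over the list alone; median −0.30), with Gpd1, the glycerol phosphate dehydrogenase, at −1.34 (SE 0.21), the insulin-responsive glucose transporter Slc2a4 at −0.92 (SE 0.17) and Orm1 at 0.78 (SE 0.17). The camera test gave 0.00114, and adjusted p = 0.158 with an estimated correlation. The fatty acid synthesis list was not called: 4 of 21 fell and 2 rose, with Acaca, the rate-limiting enzyme of the pathway, at −1.84 (SE 0.26) and Elovl6 at 1.74 (SE 0.21), and camera gave 0.0639. The pyruvate carboxylase control ratio was −0.09 at 3wk and −2.37 at 6wk.

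The 6wk arrays gave the largest count against 3wk, 2522 probe sets, 1681 higher and 841 lower (1500 genes; 5337 at an unadjusted p under 0.05), and 32.6% of probe sets had no overlap, against 10% by chance. Without 6wk A 1564 were called, and without 6wk A and B together 740, where 6wk C is the lone 6wk array and is taken to vary like the other ages, so fewer arrays and the RNA of those left out are not told apart. All 8 probe sets named above kept their call when any 1 array was left out; Ucp1 lost its call without 3wk A or 6wk A.

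At 5wk, against 3wk, Il17b rose by 5.84 (SE 0.90), Csn1s2a by 4.89 (SE 0.64), Chil1 by 4.58 (SE 0.43) and Clca1 by 4.44 (SE 0.92), with n = 2 arrays at 5wk. Cpn2 fell by 4.67 (SE 0.64), Agt by 4.12 (SE 0.49), Fabp3 by 3.77 (SE 0.39) and Kcnk3 by 3.28 (SE 0.46). Krt8 rose by 1.66 (SE 0.38), Krt14 by 1.52 (SE 0.23) and Csn2 by 2.99 (SE 0.61), while Ucp1 (−2.05, SE 0.64) did not pass.

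Camera called 7 lists upwards and 4 downwards from 3wk to 5wk, none with an estimated correlation. Luminal genes rose in 21 of 28 (27 adjusted over the list alone; median 1.72), with Epcam at 2.72 (SE 0.30) and Krt7, another keratin, at 2.37 (SE 0.46). The camera test gave an adjusted p of 1.69e-26, and adjusted p = 0.101 with an estimated correlation. Milk genes rose in 9 of 18 (10 rose and 1 fell when adjusted over the list alone), among them Lalba, alpha-lactalbumin (3.01, SE 0.45), while Glycam1, also a milk protein, was low at 5wk without passing (−5.74, SE 2.04). Camera gave 7.68e-08, and adjusted p = 0.101 with an estimated correlation. Oxidative phosphorylation genes fell in 10 of 37 (29 adjusted over the list alone; median −0.55). Their adjusted p by camera was 3.63e-20, and adjusted p = 0.104 with an estimated correlation. Basal genes rose in 5 of 19 (11 rose and 1 fell when adjusted over the list alone; median 0.91). The adjusted p from camera was 4.95e-07, and adjusted p = 0.103 with an estimated correlation. Hormone-responsive genes rose in 5 of 20 and 1 fell (7 and 1 adjusted over the list alone), with Gata3 at 3.20 (SE 0.48) and Foxa1 at 2.08 (SE 0.29). The adjusted p by camera was 0.00302, and adjusted p = 0.25 with an estimated correlation. Brown adipocyte genes fell in 7 of 13 (10 adjusted over the list alone; median −1.30). The camera test gave an adjusted p of 1.38e-10, and adjusted p = 0.0774 with an estimated correlation. The count was 670 probe sets, 441 higher and 229 lower (493 genes; 3271 at an unadjusted p under 0.05), and 34.3% had no overlap, against 20% by chance for 3 arrays against 2. It was 277 without 5wk A and 195 without 5wk B, where the lone 5wk array is taken to vary like the other ages, and 59 in a fit of these 5 arrays alone; Il17b lost its call without 5wk B, Clca1 in 4 of the 14 such fits, Krt8 without 3wk A, 5wk A or 5wk B, Krt14 without 5wk A and Csn2 without 3wk B, 5wk A or 5wk B.

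**Figure D3:**
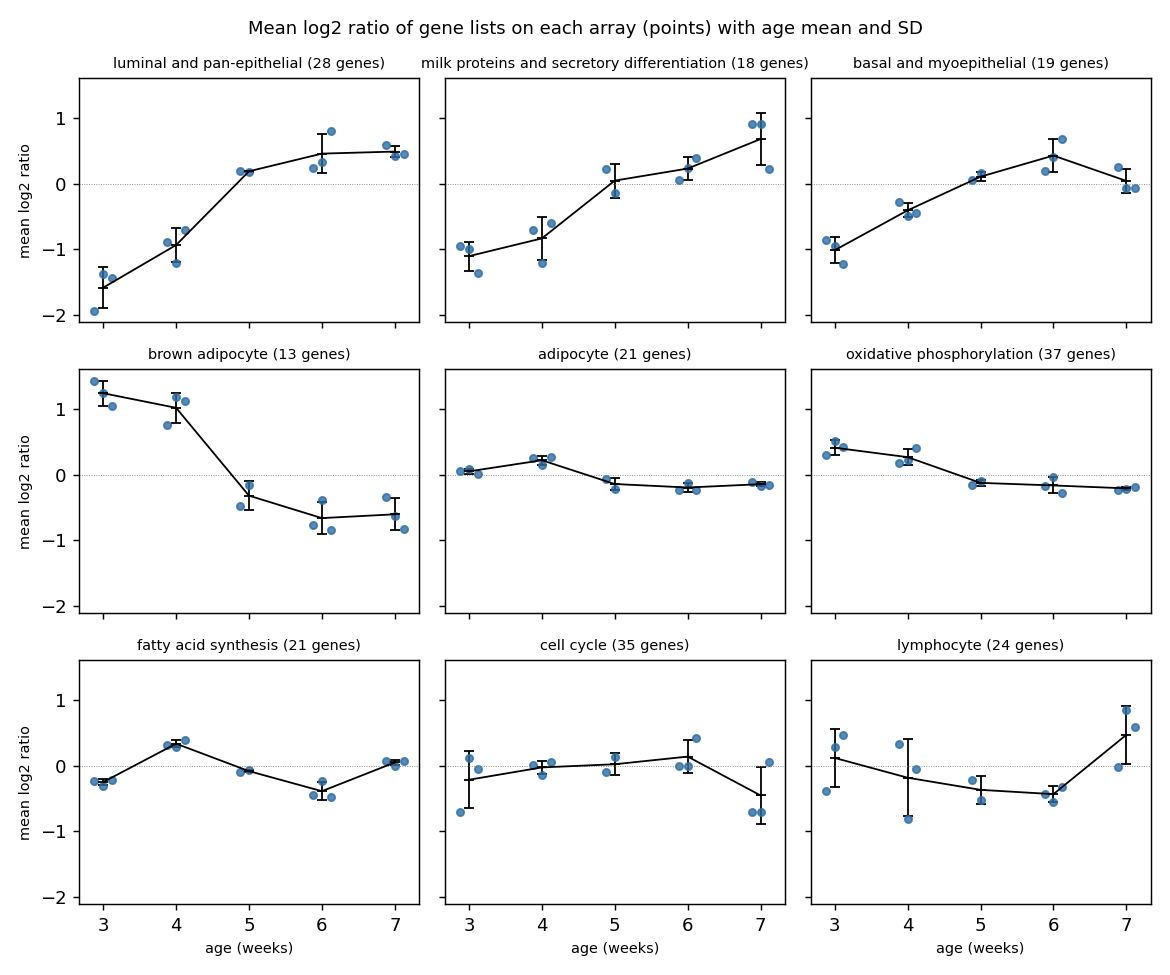
Mean log2 ratio of the genes of 9 lists on each of the 14 arrays, against age in weeks. Each point is 1 array, and the line and bars give the mean and SD of the arrays of an age; the luminal list goes from −1.58 at 3wk to 0.49 at 7wk and the brown adipocyte list from 1.24 to −0.60.

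For the first week, 3wk to 4wk, few probe sets were called. Elovl6, the elongase of long fatty acids, had the smallest adjusted p and rose by 2.25 (SE 0.24, adjusted p = 0.00929), and its 2 probe sets moved together. Ppp2r5c, a regulatory subunit of protein phosphatase, rose by 2.54 (SE 0.34), Nrgn, a calmodulin-binding protein, by 1.68 (SE 0.24) and Tmem79, a membrane protein, by 1.63 (SE 0.24). Wfdc1, a secreted protease inhibitor, fell by 2.07 (SE 0.31), Anxa8 by 1.55 (SE 0.25) and Phgdh, the first enzyme of serine synthesis, by 0.96 (SE 0.14). Of 21 fatty acid synthesis genes, 2 rose (13 adjusted over the list alone; median 0.58), Elovl6 and the desaturase Scd2 (0.79, SE 0.12), while Acaca stood at 1.37 (SE 0.26) and did not pass. Camera's adjusted p for the list was 3.14e-13, and adjusted p = 0.0774 with an estimated correlation. Luminal genes had a median of 0.72 with none passing over all genes (10 rose when adjusted over the list alone). The adjusted p by camera was 3.51e-09, and adjusted p = 0.246 with an estimated correlation. Camera called 8 lists upwards and 4 downwards at 4wk against 3wk. In the basal list Cnn1 rose by 2.09 (SE 0.29), 1 of 19 (1 adjusted over the list alone; adjusted p = 0.000157 by camera, and adjusted p = 0.178 with an estimated correlation).

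No member of the 4 lists called downwards passed over all genes. Interferon response genes had a median of −0.29 (0 of 25 adjusted over the list alone) and an adjusted p of 2.73e-06 by camera, with adjusted p = 0.16 with an estimated correlation. Oxidative phosphorylation genes had a median of −0.13 (0 of 37 adjusted over the list alone) and 5.15e-05 by camera, with adjusted p = 0.446 with an estimated correlation. For lymphocyte genes the median was −0.33 (0 of 24 adjusted over the list alone), with 0.00482 by camera and adjusted p = 0.513 with an estimated correlation. Brown adipocyte genes had a median of −0.06 (1 of 13 fell when adjusted over the list alone), with 0.0251 by camera and adjusted p = 0.372 with an estimated correlation. The array means of all 4 lists overlapped between 3wk and 4wk, and the lymphocyte list lost its call without 4wk B and the brown adipocyte list without 3wk A or 4wk A.

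In all 28 probe sets were called between 3wk and 4wk, 25 higher and 3 lower (19 genes), against 1895 at an unadjusted p under 0.05, and 15.2% had no overlap, against 10% by chance. In simulated data of this comparison with 200 of 18535 probe sets changed, 40.3% of those changed 2-fold and 82.1% of those changed 4-fold were called. The control spikes averaged 0.153 at 3wk and 0.696 at 4wk, and with them as a covariate 8 probe sets were called. Leaving out 1 array gave 6 without 3wk C, 0, 7 and 4 without 4wk A, B or C, 16 without 6wk B, and 8, 17 and 15 without 7wk A, B or C. All 7 named probe sets lost their call in at least 1 of the 14 such fits, Elovl6 only without 4wk A.

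From 4wk to 5wk, Csn1s2a rose by 5.13 (SE 0.64), Mycl by 3.77 (SE 0.24) and Crabp2, a retinoic acid carrier, by 3.40 (SE 0.44). For Csn2, 1 probe set rose by 3.48 (SE 0.64), but the mean over its probe sets did not pass (2.87, SE 0.61, adjusted p = 0.055). Cpn2 fell by 3.98 (SE 0.64), Kcnk3 by 3.77 (SE 0.46), Cpz, a carboxypeptidase, by 3.53 (SE 0.68) and Ppara by 2.77 (SE 0.37). Luminal genes rose in 3 of 28 (25 adjusted over the list alone; median 1.19), with the keratin Krt19 at 1.55 (SE 0.38) not passing. The adjusted p by camera was 2.32e-21, and adjusted p = 0.101 with an estimated correlation. Brown adipocyte genes fell in 3 of 13 (9 adjusted over the list alone; median −1.16), with Fabp3 at −2.43 (SE 0.39), camera's adjusted p at 2.21e-09 and adjusted p = 0.0774 with an estimated correlation. In the adipocyte list 0 of 21 passed over all genes and 8 fell when adjusted over the list alone (median −0.41). This list had, by camera, an adjusted p of 4.72e-06, and adjusted p = 0.101 with an estimated correlation. Oxidative phosphorylation genes fell in 1 of 37, Etfdh (−0.97, SE 0.17), an electron carrier of fat oxidation (16 adjusted over the list alone). In camera the list had an adjusted p of 1.25e-13, and adjusted p = 0.158 with an estimated correlation. Fatty acid synthesis genes fell in 1 of 21, Acaca (−1.87, SE 0.28; 5 adjusted over the list alone; camera 2.73e-06, and adjusted p = 0.104 with an estimated correlation). In all, camera called 7 lists upwards and 8 downwards in this step. The actin control ratio was 0.20 at 4wk and −0.21 at 5wk.

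This step gave 139 probe sets, 58 higher and 81 lower (44 genes; 2764 at an unadjusted p under 0.05), and 33.5% had no overlap, against 20% by chance. The control spikes averaged 0.696 at 4wk and −0.115 at 5wk, and with them as a covariate the count was 16. Leaving out 1 array gave 85 without 3wk C, 50, 12 and 61 without 4wk A, B or C, 81 and 53 without 5wk A or B, and 77, 74 and 76 without 7wk A, B or C. A fit of these 5 arrays alone gave 2. Csn1s2a, Mycl and Kcnk3 kept their call whichever array was left out, Crabp2 and Ppara lost it without 4wk B, and Csn2, Cpn2 and Cpz lost it in 11, 4 and 11 of the 14 such fits.

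Between 5wk and 6wk few probe sets were called, and most of those were lower at 6wk. Malat1 fell by 3.98 (SE 0.59), Cdk6, a cell cycle kinase, by 3.21 (SE 0.47), Zbtb20, a zinc finger repressor, by 2.71 (SE 0.47) and Sfpq, a splicing factor, by 2.10 (SE 0.33). Slc25a13, a mitochondrial aspartate and glutamate carrier, rose by 2.62 (SE 0.40), Mbl1, a mannose-binding lectin, by 1.98 (SE 0.28), the arginine transporter Slc7a2 by 1.49 (SE 0.25) and Ppp1r8, a nuclear phosphatase inhibitor, by 1.40 (SE 0.16). The 44 falls coincided with a lower pyruvate carboxylase control ratio at 6wk (−2.37 at 6wk and −0.95 at 5wk). Camera called 1 list upwards and 4 downwards, and no member of any list passed over all genes. The fatty acid synthesis list had a median of −0.28 (2 of 21 fell when adjusted over the list alone; Acaca −1.34, SE 0.28), camera's adjusted p of 6.97e-07 and adjusted p = 0.101 with an estimated correlation. Cholesterol synthesis genes had a median of −0.20 (0 of 19 adjusted over the list alone), camera's adjusted p of 0.000899 and adjusted p = 0.255 with an estimated correlation.

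The count was 52 probe sets, 8 higher and 44 lower, with 1944 at an unadjusted p under 0.05, while limma called 0 of 10703 genes on the mean of their probe sets; 28.9% had no overlap, against 20% by chance. It fell to 17 and 30 without 3wk B or C, 14, 25 and 30 without 4wk A, B or C, 33 without 5wk B, 10 and 15 without 6wk A or B, and 25, 24 and 17 without 7wk A, B or C. Of the 8 named probe sets, that of Ppp1r8 alone kept its call in all 14 such fits.

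From 6wk to 7wk most called probe sets rose. Fscn1, an actin-bundling protein, rose by 4.05 (SE 0.61), the survival factor Bcl2l1 by 3.79 (SE 0.50), Ywhag, a 14-3-3 protein, by 3.52 (SE 0.50) and Ttyh2, a membrane channel protein, by 3.13 (SE 0.53). The keratin Krt15 fell by 3.80 (SE 0.71), Nepn, a small proteoglycan, by 2.33 (SE 0.40), Slc25a13 by 2.26 (SE 0.36) and Tpd52l1 by 1.95 (SE 0.34). Fatty acid synthesis genes rose in 3 of 21 (4 adjusted over the list alone; median 0.27), among them Acaca (2.66, SE 0.26) and Scd2 (1.46, SE 0.12), and the 3 probe sets of Scd2 differed in size, at 2.95, 0.97 and 0.46. The adjusted p from camera was 3.48e-06, and adjusted p = 0.105 with an estimated correlation. The Scd2 probe set at 2.95 is among the 29 low at 6wk alone that are described further below. The list's mean was −0.247, 0.336, −0.082, −0.387 and 0.050 at 3wk, 4wk, 5wk, 6wk and 7wk. It was lowest at 6wk, as was the pyruvate carboxylase control ratio. RNA quality and a change of the gland are not told apart for this list. The cell cycle list had a median of −0.56, with 0 of 35 passing over all genes and 8 falling when adjusted over the list alone. Its mean was −0.710 and −0.698 on 7wk A and B but 0.055 on 7wk C, against −0.009, 0.002 and 0.427 on 6wk A, B and C. Bub1b, a spindle checkpoint kinase, stood at −1.96 (SE 0.67), Mki67 at −1.58 (SE 0.45) and Ube2c, a ubiquitin enzyme of mitosis, at −1.52 (SE 0.41). The test of camera gave them an adjusted p of 1.33e-10, and adjusted p = 0.347 with an estimated correlation. The lymphocyte list had a median of 0.61 with 0 of 24 passing either way (0 adjusted over the list alone), the largest differences being Ltb, lymphotoxin beta (4.04, SE 1.11), and the T cell receptor chain Cd3d (3.04, SE 1.38). Camera's adjusted p was 2.72e-07, and adjusted p = 0.241 with an estimated correlation. The list's mean was 0.12, −0.18, −0.37, −0.43 and 0.47 at 3wk, 4wk, 5wk, 6wk and 7wk. Camera also called it downwards at 5wk and 6wk against 3wk (adjusted p 0.0125 and 0.00559, and 0.547 and 0.515 with an estimated correlation), with array means that overlapped. Cholesterol synthesis genes had a median of 0.43, with 0 of 19 passing over all genes and 4 rising when adjusted over the list alone. For these genes camera gave an adjusted p of 0.000123, and adjusted p = 0.21 with an estimated correlation. In all, camera called 3 lists upwards and 3 downwards. Csn2 stood at 2.58 (SE 0.55) without passing.

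In this last week 177 probe sets were called, 153 higher and 24 lower (38 genes; 2591 at an unadjusted p under 0.05), and 20.8% had no overlap, against 10% by chance. The pyruvate carboxylase control ratio was −2.37 at 6wk and 0.82 at 7wk, and the control spikes −0.15 and −1.21. The count was 18 with the spikes as a covariate, and 33 without 6wk A and B, which leaves 6wk C alone with a spread taken from the other ages. Leaving out 1 array gave 116 without 4wk A, 62, 73 and 272 without 6wk A, B or C, and 51, 43 and 62 without 7wk A, B or C; Bcl2l1 and Ywhag kept their call in all 14 such fits, and the other 6 named probe sets did not.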

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

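For counts that other settings changed, the cause was not tested unless said. Planned but not run were the filter on the 60th percentile, because the absolute level had been removed, and empirical Bayes with a trend and a robust fit together, because the trend needs the absolute level. Added after the data were seen were the stricter filter of 400 steps, offsets of 16 and 0.1, a robust fit with no trend, 6wk A and B left out, the control spikes as a covariate, and 1 probe set per gene.

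A 2-fold bound, which can only lower a count, left 1141 of 1904 probe sets for any age, 401 of 670 for 5wk against 3wk, 1015 of 2522 for 6wk against 3wk and 697 of 1575 for 7wk against 3wk. Fits of only the arrays of 2 ages, with fewer arrays to estimate the spread, gave 0 of 28 for 4wk against 3wk, 59 for 5wk against 3wk, 808 for 6wk against 3wk, 604 for 7wk against 3wk, 2 of 139 for 5wk against 4wk, 2 of 52 for 6wk against 5wk and 10 of 177 for 7wk against 6wk, and 36 of the 71 named genes. Without 6wk A and B, which leaves 1 array at 6wk, the counts were 1012 for any age, 740 for 6wk against 3wk, 11 for 6wk against 5wk and 33 for 7wk against 6wk. With the control spikes as a covariate they were 1033 for any age, 8 for 4wk against 3wk, 351 for 7wk against 3wk, 16 for 5wk against 4wk, 32 for 6wk against 5wk and 18 for 7wk against 6wk, and 40 named genes were called.

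For 4wk against 3wk, quantile normalization gave 8, no filter 9, and offsets of 0.1, 1, 16 and 64 gave 17, 11, 14 and 15. For 5wk against 4wk, quantile normalization gave 262, no filter 73, the stricter filter 210, an offset of 1 gave 218 and array weights 292. For 6wk against 5wk, quantile normalization gave 33, and offsets of 1, 16 and 64 gave 14, 6 and 6. No filter gave 95 for 7wk against 6wk. Quantile normalization also moved the share of called probe sets that rose, from 89.3% to 100% for 4wk against 3wk, from 69.6% to 55.5% for 7wk against 3wk and from 86.4% to 71.4% for 7wk against 6wk, while it kept 90.8% of the calls for any age. With 1 probe set per gene, Krt14 stood at −0.047 for 6wk against 3wk, where the mean of its 3 probe sets was 1.65, because the probe set taken is the one that did not move.

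Taking the replicate letter as a block gave 9 for 4wk against 3wk, 35 for 5wk against 4wk and 2 for 6wk against 5wk. The 26 pairs of arrays with the same letter and different ages had correlations of −0.064 to 0.089 (median 0.014, against −0.01 for the other 52 pairs). Of the 14 arrays, 8 had their best match at another age in an array of the same letter, and the number due to chance was not computed. A weak pairing by letter is thus not excluded. The design fixed before the data were examined had no block, and this was kept.

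Of the 79 list calls, 0 held with an estimated correlation. Leaving out 1 array gave 72 to 92 list calls, and 56 of the 79 held throughout. The same fits gave 1342 (without 7wk C) to 1671 for any age, 0 to 29 for 4wk against 3wk, 195 to 623 for 5wk against 3wk, 1564 to 2428 for 6wk against 3wk, 923 to 1528 for 7wk against 3wk, 12 to 201 for 5wk against 4wk, 10 to 46 for 6wk against 5wk and 43 to 272 for 7wk against 6wk. Of the 71 named genes 53 to 62 were called in each such fit, 40 in all of them, and 24 in every setting in which they were tested. The stricter filter left 58 of the 71 to test. The counts moved by more than 1.5-fold without 5wk A or B for 5wk against 3wk, 6wk A for 6wk against 3wk, each 7wk array for 7wk against 3wk, and each of 8, 9, 11 and 7 of the 14 arrays for 4wk against 3wk, 5wk against 4wk, 6wk against 5wk and 7wk against 6wk.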

Other observations

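The regroupings of arrays were planned before the data were examined, and all other tests in this section were chosen after the results were seen. In this section the SE of a median comes from redrawing genes or probe sets. Genes that move together make it smaller than the spread between pools. The SE of a difference between list means comes from the spread of the arrays. For any age, 1 of 100 groupings, the real one, called as many as 1904 probe sets, and the highest other called 10. For 4wk against 3wk, 6wk against 3wk, 7wk against 3wk and 7wk against 6wk, 1 of 10 splits each, the real one, called as many, and the highest others called 3, 0, 3 and 2, but 10 splits are too few for a share below 0.05. For the gene lists 5 of 100 groupings, the real one included, gave at least 79 calls, the highest other 87, so chance is not excluded for the number of list calls.

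Of 13 brown adipocyte genes 7, 9 and 8 fell at 5wk, 6wk and 7wk against 3wk, though the list was not called with an estimated correlation (adjusted p = 0.0774). Against the values of 7wk and 3wk, which were known by then, 3 readings were set. Fewer fat cells of every kind would lower general adipocyte genes as much, but the brown list fell by more than the adipocyte list, with a difference of −1.649 (SE 0.165). Muscle left on the younger glands would lower muscle genes as well, and the difference from the muscle list was −1.774 (SE 0.278). At 7wk the mean actin and pyruvate carboxylase control ratios were at least as high as at 3wk. Loss of 5' signal on the 5wk and 6wk arrays would thus leave 7wk unchanged, yet the list stood at −1.844 (SE 0.179) there. That value is the fall for which the list was taken up, so it is no independent test. Other technical differences of the 7wk arrays are not covered, as their control spikes averaged −1.21 against 0.15 at 3wk. Hypothesis: brown or beige adipocytes may become a smaller part of the gland fat between 3wk and 7wk, and counts of UCP1-positive cells in sections of 3wk to 7wk glands could test it.

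A set of 29 probe sets fell from 5wk to 6wk and rose again by 7wk, where 0.36 would do both if falls and rises were independent. In 50 simulations without change, the 44 lowest-ranked for the fall and 153 highest-ranked for the rise were taken, called or not. They shared a median of 11 and at most 18. The simulated noise was independent between probe sets, so a cause shared by many probe sets was not covered. The 29 depend on the 52 calls between 5wk and 6wk, which were 10 without 6wk A, 14 without 4wk A and 15 without 6wk B. The 153 probe sets that rose from 6wk to 7wk had a median of −0.464 (SE 0.058) from 4wk to 5wk, the direction of the actin and pyruvate carboxylase control ratios. The other 42 probe sets of the same genes had a median of −0.066 (SE 0.079) and the 29 a mean of −1.631 on 6wk C (SD of the arrays of other ages 0.116), but both values rest on probe sets sorted by the same change, so neither a change of whole transcripts nor poor RNA on 6wk A and B alone is excluded. Hypothesis: part of the dip at 6wk, which all 5 probe sets of Malat1 showed (−0.701 to −3.28), might come from RNA quality, and quantitative PCR near the 3' end of Malat1 could test it.

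The immunoglobulin A genes Igha and Jchain rose from 3wk to 7wk, and lymph node left in the 7wk glands could raise them. The other lymphocyte genes had a median of only 0.224 (SE 0.072 over genes), which speaks against that reading. The mean of the lymphocyte list had an SD of 0.447 between the 3wk arrays and 0.444 between the 7wk arrays. The pools thus differed by more than this SE shows. From 6wk to 7wk the lymphocyte list, whose mean was lowest at 6wk (−0.433) and highest at 7wk (0.471), had a median difference of 0.612 (SE 0.086), and that test did not decide between lymph node and lymphocytes of the gland. Hypothesis: plasma cells making immunoglobulin A may settle in the gland during puberty, and staining of 7wk glands for IgA could test it.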
